A study of Homo sapiens with 70 samples.

How the data were processed

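Activated CD8 T cells, sorted from blood as cells bearing CD38 and HLA-DR, were profiled by bulk RNA sequencing in 25 people with kidney cancer on checkpoint immunotherapy, per the labels. Blood was drawn before treatment (baseline, 25 libraries), at cycle 1 (25) and at cycle 2 (20), so that 20 patients gave 3 libraries and 5 gave 2. Libraries were made with a template-switching kit that does not mark the strand, per the labels' protocols. The labels give no response, dose or outcome, and their disease state field holds the cell population, so treatment effects can only be read as differences between draws.

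The authors deposited 1 table of raw read counts, with 60619 Ensembl gene IDs and 70 columns, and all 70 columns were used. Per the submitters' processing notes, reads were handled with cutadapt, HISAT2, Subread, featureCounts and DESeq2; no version, genome build or annotation release is given in the sources used here. The deposited counts were whole numbers, as raw read counts are. They summed to between 4219105 and 27926616 per library, and errors given are standard errors of the model or of differences between patients, not counting errors. For edgeR folds the error was worked back from the fold and the F statistic of its test. The column names carry 2 lane labels, L001 with 25 libraries from 9 patients and L006 with 45 libraries from 16 patients, and each patient lies within 1 lane. Symbols were taken from a table of gene names, which held 56434 of the IDs, and otherwise from GENCODE release 29. That release may not be the annotation the authors used. In all, 56927 IDs had a symbol, and IDs without one held 0.101% of the counts. No coordinates are given for this reason.

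The test of genes was edgeR 4.0.16 (quasi-likelihood F test with robust dispersion, TMM factors, filterByExpr with a count minimum of 10), with the patient as a block and the draw as the term of interest, on all 70 libraries. It tested 15553 genes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Cycle 1 against baseline, cycle 2 against baseline and cycle 2 against cycle 1 were read from that model, together with a joint test of any change over the 3 time points. The biological coefficient of variation was 0.658, and TMM factors ran from 0.0167 to 1.7, the next lowest being 0.108.

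Before the data were examined, 30 gene lists (20 on biology and 10 of markers of other cell types), the main model, the alternatives to it and the rule for naming genes were fixed. The biology lists were S phase and DNA replication, mitosis, cytotoxic effector, terminal effector, stem and memory, inhibitory receptor and exhaustion, MHC class II presentation, costimulation and activation, type I interferon response, interferon gamma response, homing and chemokine receptors, NK-type receptors on T cells, oxidative phosphorylation, glycolysis, immediate early and heat shock, glucocorticoid response, p53 and apoptosis, T cell receptor signalling, ribosomal proteins and mitochondrially encoded genes. The marker lists were for CD4 and regulatory T cells, gamma-delta and MAIT cells, NK cells, B cells, plasma cells, monocytes, dendritic cells, neutrophils, platelets and erythroid cells. Of their symbols 611 were found and 11 were not, the latter being older or alias names. Lists were tested with camera in limma 3.58.1 on voom log2 values under the same model, with a preset correlation of 0.01, adjusted over the 30 lists of a comparison. Beside it stand camera with an estimated correlation and fry, a rotation test of whether members move, on balance, in 1 direction. Medians and means of a list are those of the voom fit, while folds of single genes and counts of members above 0 are from edgeR unless another tool is named.

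The rule for naming genes takes, per comparison, up to 10 passing genes each way. They need a mean of at least 5 CPM (counts scaled to the library total) and the fitted direction in most pairs. Where none pass, it takes the 3 of smallest p each way, given as not passing. It adds up to 4 members of smallest p of each list and 25 genes fixed in advance, among them the sorting markers CD38, HLA-DRA and HLA-DRB1. Sex-linked transcripts used only for label checks, receptor gene segments, genes without a symbol and clone or antisense loci were left out of the rule. CPM values are scaled by the TMM factors, except the levels of CD38 and HLA-DRA per library, which are scaled to the total without mitochondrially encoded counts.

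A score per patient was computed for each list as the mean log2 of CPM plus a pseudocount of 1 over its members. Differences within patients were tested with a two-sided sign-flip permutation test (100000 resamples, exact where 16 or fewer pairs were available) and adjusted over the 30 lists. The breadth of T cell receptor beta V (TRBV) gene use was the Shannon entropy, with the natural log, of the shares of TRBV genes among TRBV counts, thinned to 500 counts per library. Libraries with fewer were left out. Similarity of TRBV use, tested one-sided by permuting patient labels, was 1 minus the halved sum of absolute differences of shares. Differences between lanes were tested by permutation of the lane labels over patients. Pearson and Spearman correlations across patients were computed for 6 relations fixed in advance, with permutation p values.

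Alternatives were run with DESeq2 1.42.0 size factors and its Wald test, limma voom with and without quality weights and with the patient as a random effect, no low count filter and a count minimum of 50. Others were no patient block, added covariates, a threshold of 0.1, pseudocounts of 0.25 and 5, subsets of libraries, and TRAV in place of TRBV genes. In all, 29 alternatives of the gene tests were run, of which 13 were planned and 16 were added after the data were seen. The added ones concern the lane labels, limma voom without weights, the 5 libraries that stand apart (over 50% mitochondrial counts or over 30000 genes with a count), and 10 doubted libraries. The doubted libraries are those 5, the 6 with fewer than 10 CPM of CD38 (scaled to the library total without mitochondrially encoded counts), and 2 that did not match the other libraries of their patient, with overlaps between these groups. Time labels were shuffled within patients 20 times, and 40 times within L006.

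The gene test was checked on simulated counts of 15845 genes with changes of 3 known sizes. For cycle 1 against baseline it recovered 24 of 67 genes changed 1.5-fold (35.8%), 64 of 67 changed 2-fold (95.5%) and 66 of 66 changed 4-fold (100%), and it called 5 unchanged genes. For cycle 2 against baseline the recovered numbers were 17 of 67 (25.4%), 59 of 67 (88.1%) and 66 of 66 (100%), with 7 unchanged genes called. The simulated libraries held no failed samples, and their spread was set below the coefficient of variation of 0.658 fitted to the real ones. The recovered shares are therefore not the power of the test on the real libraries. Work was done in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.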

Results

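The data are bulk RNA-seq counts from activated CD8 T cells, sorted as CD38+ HLA-DR+ cells from the blood of 25 people with kidney cancer on checkpoint immunotherapy. Libraries were made before treatment (baseline, n = 25), at cycle 1 (n = 25) and at cycle 2 (n = 20), with 20 patients measured at all 3 time points. Total counts per library ran from 4219105 to 27926616 with a median of 16549737. The medians were 16484393 at baseline, 16410653 at cycle 1 and 17386138.5 at cycle 2, and 3 libraries had less than 50% of the overall median. The median library had counts in 20281.5 genes. In each case the question was how the activated CD8 T cells in blood differed between draws, since the labels hold no outcome.

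CD38, an ectoenzyme used to sort the cells, had a median of 75.3 CPM at baseline, 112.8 at cycle 1 and 96.4 at cycle 2. In this paragraph CPM are counts scaled to the total of a library without its mitochondrially encoded counts, and after it they are scaled by TMM factors. HLA-DRA, the class II chain of the other sorting marker, had medians of 736, 788 and 825 CPM. The 45 libraries of lane label L006 (16 patients) held 3.33 to 19.7% mitochondrially encoded counts, with a median of 7.19%. In the 25 libraries of lane label L001 (9 patients) the median was 10.7% and the highest value 96.3%. Of the L001 libraries, 4 held over 50% mitochondrial counts and 1 had counts in over 30000 genes. These 5 libraries, from 3 patients, were 2 of baseline, 2 of cycle 1 and 1 of cycle 2. On that scale CD38 was under 10 CPM in 6 L001 libraries, 4 of baseline and 2 of cycle 2, and in 0 of L006. A further check found that 2 libraries did not match the other libraries of their patient. Together these make 10 doubted libraries, 5 at baseline, 2 at cycle 1 and 3 at cycle 2. The baseline libraries with little CD38 were not all alike. Those with CD38 at 0.59 and 7.41 CPM had HLA-DRA at 49.4 and 31.4 CPM, against at least 402.5 CPM in L006. Their mitochondrial shares were 6.4 and 7.46%. Those with CD38 at 1.27 and 2.87 CPM had HLA-DRA at 3028 and 176.9 CPM, and mitochondrial shares of 62.7 and 24.1%. Whether libraries low in both sorting markers hold activated cells was not tested.

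**Figure D1:**
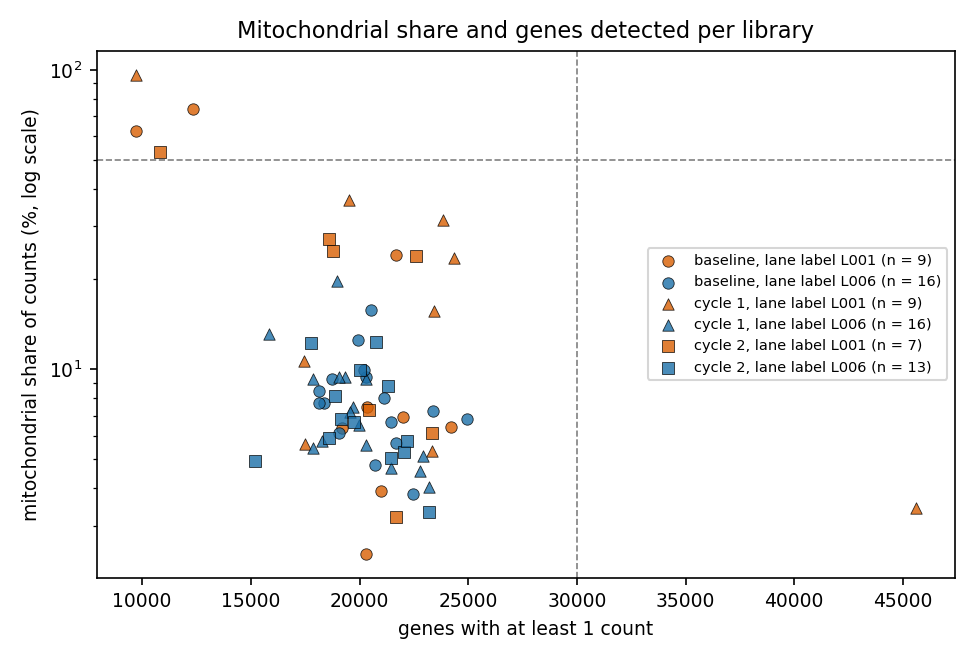
Share of mitochondrially encoded counts (percent, log axis) against the number of genes with a count, 1 point per library, by time point and lane label. The 45 L006 libraries lie between 3.33 and 19.7%, and the 5 points beyond the dashed lines (50% and 30000 genes) carry L001.

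Libraries of the same patient resembled each other in L006 far more than in L001. After the mean of each time point was removed, the mean correlation across genes (which are not independent replicates) was 0.446 over 42 pairs of L006 libraries that share a patient. It was 0.0583 over 23 such L001 pairs. The nearest library of another time point came from the same patient for 39 of 45 L006 libraries and for 5 of 25 L001 libraries. Over both lanes these were 0.35 (65 pairs) and 45 of 70. Without the 10 doubted libraries, all of L001, they were 0.415 (50 pairs, both lanes) and 42 of 58. The L001 pairs without a doubted library were not examined alone. With all L001 libraries kept, then, changes within patients and the patient block rest on patient labels that those libraries bear out only weakly. How far this holds beyond the doubted libraries was not tested.

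At cycle 1 the sorted cells had more transcript of the cell division machinery than at baseline, where some libraries were low in both sorting markers. All 40 measured genes of the mitosis list were above baseline, with a median log2 change of +0.66 (camera adjusted p = 1.38e-15; adjusted p = 0.313 with an estimated correlation). MKI67, a marker of cycling cells, went from a mean of 163.9 to 257.2 CPM (log2 +0.90 ± 0.45 SE, n = 25, higher in 19 pairs, p = 0.050 unadjusted). CENPF and CENPE, which act at kinetochores, had log2 changes of +1.00 ± 0.38 and +1.02 ± 0.40. The spindle motor KIF11 had +0.80 ± 0.36 and the topoisomerase TOP2A +0.86 ± 0.44. All 35 genes of the S phase and DNA replication list were above baseline too (median +0.44, adjusted p = 6.59e-14; adjusted p = 0.313 with an estimated correlation). Among these, the polymerase alpha subunit POLA1 was higher in 21 of 25 pairs (+0.48 ± 0.20) and the chromatin factor ATAD2 in 18 (+0.64 ± 0.27). The mitosis score per patient was +0.67 ± 0.24 (SE, n = 25), higher in 17 pairs, with a two-sided permutation p of 0.011 and an adjusted p of 0.131. It was +1.28 in L001 and +0.32 in L006 (difference between lanes, exact permutation p = 0.058, adjusted p = 0.16). In L001 it was +1.77 ± 0.76 in the 5 pairs with a doubted library and +0.67 ± 0.79 in the other 4. Without the 10 doubted libraries it was +0.39 ± 0.21 (n = 20, p = 0.073).

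Interferon gamma response genes were also higher at cycle 1, by a small amount in most patients. Of 24 members, 20 were above baseline (median +0.17, adjusted p = 1.93e-04; adjusted p = 0.196 with an estimated correlation). The guanylate-binding protein GBP1 was higher in 23 of 25 pairs (log2 +0.50 ± 0.21), GBP5 in 20 (+0.44 ± 0.24) and GBP2 in 20 (+0.31 ± 0.18). The score per patient was +0.16 ± 0.06, higher in 21 of 25 patients (permutation p = 0.0099, adjusted p = 0.131). It was +0.15 in L001 and +0.16 in L006 (exact permutation p of the difference 0.95). The L001 mean joins +0.41 ± 0.15 in 5 pairs that hold a doubted library with -0.17 ± 0.16 in the other 4. With the 10 doubted libraries left out the score was +0.10 ± 0.05 (n = 20, higher in 17, p = 0.087, adjusted p = 0.452), which did not pass. In L006 alone it passed (higher in 15 of 16 patients, exact p = 0.0013, adjusted p = 0.038). The type I interferon response list had a median of +0.08 and did not pass (adjusted p = 0.37), with ISG15 at +0.10 ± 0.20.

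**Figure D2:**
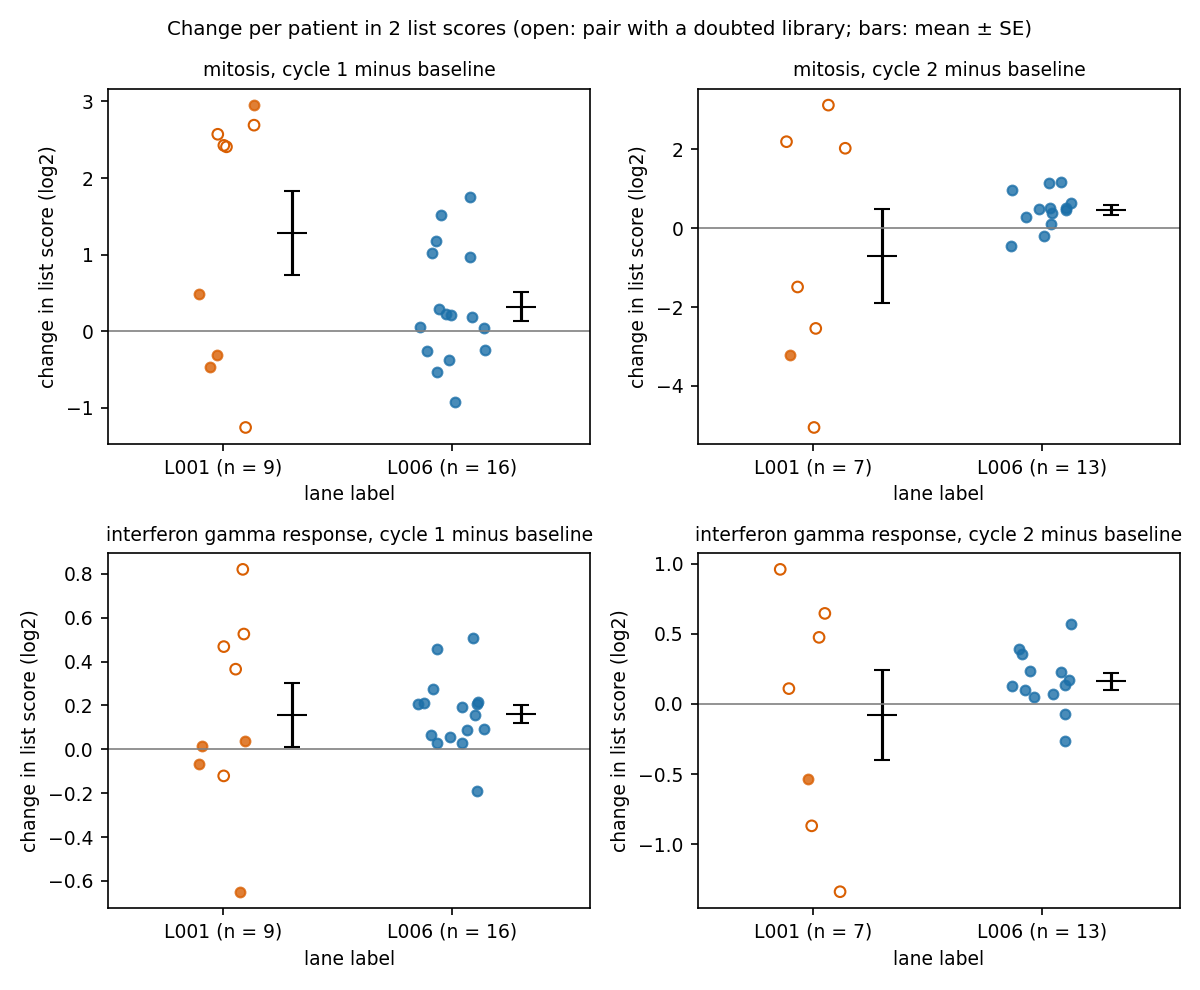
Change in the mitosis and interferon gamma response scores per patient (mean log2 CPM over members) from baseline to cycle 1 and to cycle 2, by lane label; open points are pairs with a doubted library, bars are mean ± SE. At cycle 1 the interferon gamma score was higher in 21 of 25 patients and the mitosis score in 17.

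Inhibitory receptor genes were higher at cycle 1 in the list test, though not in the L001 pairs without a doubted library. Homing genes passed with all libraries but not without the doubted ones. The inhibitory receptor and exhaustion list had a median of +0.39 with 16 of 22 genes above baseline (adjusted p = 2.08e-04; adjusted p = 0.196 with an estimated correlation). CTLA4, an inhibitory receptor (ENSG00000163599), had a log2 change of +0.83 ± 0.35 and mean levels of 10.3 and 15.2 CPM, and PDCD1, which encodes PD-1, had +0.72 ± 0.35 (higher in 19 of 25). LAG3 had +0.52 ± 0.28, the exhaustion regulator TOX +0.50 ± 0.31, TIGIT +0.33 ± 0.29 and HAVCR2 +0.28 ± 0.35. In the homing list (median +0.12, 15 of 19 above baseline, adjusted p = 0.018; adjusted p = 0.395 with an estimated correlation), CXCR6 had +0.92 ± 0.43, CXCR3 +0.58 ± 0.24 and ITGAE, the CD103 integrin chain, +0.43 ± 0.22. Leaving out the 10 doubted libraries, the medians were +0.16 for inhibitory receptors (adjusted p = 0.022; adjusted p = 0.343 with an estimated correlation) and -0.072 for homing (adjusted p = 0.93). In L006 they were +0.17 (adjusted p = 0.015; adjusted p = 0.229 with an estimated correlation) and +0.00048 (adjusted p = 0.286). The inhibitory receptor score changed by +0.18 ± 0.07 in L006 (higher in 12 of 16 pairs). In L001 it changed by +1.07 ± 0.39 in the 5 pairs with a doubted library. In the other 4 it changed by -0.19 ± 0.14, with 1 higher. With quality weights in limma, 6 genes passed. Of these GNG4, a G protein gamma subunit (ENSG00000168243), rose by a log2 of 2.97 ± 0.43 (adjusted p = 2.05e-04) from a mean of 0.65 to 4.48 CPM, while edgeR gave +1.73 ± 0.68 (p = 0.014 unadjusted) on the same libraries. CXCL13, a B cell attracting chemokine, rose by 2.19 ± 0.43 (adjusted p = 0.030; edgeR +1.13 ± 0.79, p = 0.16) from 0.96 to 3.06 CPM, and CTLA4 by 0.90 ± 0.18 (adjusted p = 0.032). PHEX rose too (+2.49 ± 0.51; edgeR +2.39 ± 0.74), and CEROX1 fell (-3.03 ± 0.61; edgeR -3.44 ± 0.92). The constant gene IGHG2 passed with the weights (-3.65 ± 0.67, adjusted p = 0.012), but edgeR gave -0.35 (p = 0.71) on the same libraries and -1.12 (p = 0.20) without the 10 doubted ones. These 6 genes were singled out after their values were seen.

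Memory and stress-type transcripts were lower at cycle 1 over all libraries, and did not pass in L006. The stem and memory list had 18 of 20 genes below baseline (median -0.41, adjusted p = 9.29e-10; adjusted p = 0.196 with an estimated correlation). The lymph node homing receptor CCR7 had a log2 change of -1.13 ± 0.45, but -0.21 in L006 alone. The interleukin 7 receptor IL7R had -0.71 ± 0.34, LTB -0.77 ± 0.28 and the transcription factor TCF7 -0.43 ± 0.26. The immediate early and heat shock list was lower (median -0.43, 20 of 25 genes below baseline, adjusted p = 4.4e-08; adjusted p = 0.196 with an estimated correlation), with JUNB at -0.65 ± 0.30 and PPP1R15A at -0.69 ± 0.32. So was the glucocorticoid response list (median -0.38, adjusted p = 1.09e-04; adjusted p = 0.196 with an estimated correlation), with TSC22D3 at -0.42 ± 0.24. In L006 the medians were +0.018 for stem and memory (adjusted p = 0.553), -0.12 for immediate early (adjusted p = 0.139) and -0.036 for glucocorticoid response genes (adjusted p = 0.846). With the 10 doubted libraries left out they were -0.13 (adjusted p = 0.063), -0.32 (adjusted p = 1.44e-05; adjusted p = 0.343 with an estimated correlation) and -0.32 (adjusted p = 0.0072; adjusted p = 0.343). The stem and memory score changed by -1.14 in L001 and +0.04 in L006 (exact permutation p of the difference 0.0011, adjusted p = 0.011), with -1.43 ± 0.68 in the 5 L001 pairs that hold a doubted library and -0.79 ± 0.39 in the other 4.

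Effector and NK-type gene groups were higher at cycle 1 in the list tests over all libraries, but not without the doubted ones. The cytotoxic effector list had a median of +0.35 (18 of 20 above baseline, adjusted p = 8.53e-05; adjusted p = 0.395 with an estimated correlation), with the granzyme GZMB at +0.56 ± 0.40, PRF1 at +0.19 ± 0.26, GZMK at +0.32 ± 0.27 and IFNG at +0.17 ± 0.38. The terminal effector list had +0.30 (adjusted p = 0.0041; adjusted p = 0.475 with an estimated correlation), with ZNF683 at +0.67 ± 0.32 and CX3CR1 at +0.29 ± 0.33. The NK-type receptors had +0.38 (adjusted p = 3.49e-04; adjusted p = 0.395 with an estimated correlation), with KLRC2 at +0.65 ± 0.37. The NK-type score changed by +1.14 in L001 and -0.16 in L006 (exact permutation p = 2.5e-04, adjusted p = 0.0076), and the terminal effector score by +1.37 and -0.12 (p = 0.0025, adjusted p = 0.019). For the cytotoxic score, higher in 12 of 25 patients, the lane values were +1.05 and -0.01 (p = 0.031, adjusted p = 0.15). The L001 means differed with the doubted libraries. In the 5 L001 pairs that hold such a library the changes were +1.73 ± 0.33 for NK-type, +2.65 ± 0.42 for terminal effector and +2.11 ± 0.89 for cytotoxic scores. In the other 4 they were +0.41 ± 0.39, -0.24 ± 0.29 and -0.29 ± 0.37. Leaving out the 10 doubted libraries gave list medians of -0.06 for cytotoxic effector genes (adjusted p = 0.389) and -0.041 for NK-type receptors (adjusted p = 0.621). The terminal effector median there was -0.16, which passed as lower (adjusted p = 0.022; adjusted p = 0.507 with an estimated correlation).

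Among the other biology lists, costimulation (+0.18, adjusted p = 0.049), oxidative phosphorylation (+0.10, adjusted p = 9.03e-04) and mitochondrially encoded genes (+0.33, adjusted p = 0.032) were higher and ribosomal proteins lower (-0.13, 40 of 40 genes below baseline, adjusted p = 9.3e-07). With an estimated correlation their adjusted p values were 0.395, 0.475, 0.686 and 0.489. Costimulation without the 10 doubted libraries had +0.072 (adjusted p = 0.203) and ribosomal proteins +0.047, and in L006 the mitochondrially encoded median was +0.0012 (adjusted p = 0.993). Medians that did not pass were +0.13 for MHC class II presentation (adjusted p = 0.119), +0.04 for T cell receptor signalling, +0.03 for p53 and apoptosis and +0.04 for glycolysis. Of the sorting markers, CD38 had a log2 change of +0.52 ± 0.36, HLA-DRA -0.03 ± 0.30 and HLA-DRB1 +0.02 ± 0.27. CD8A had +0.08 ± 0.14, CD4 -0.18 ± 0.59, ICOS +0.10 ± 0.20 and TNFRSF9 +0.52 ± 0.40.

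Markers of some other blood cells also passed at cycle 1. B cell markers were lower (median -0.44, 0 of 15 genes above baseline, adjusted p = 0.0036; adjusted p = 0.489 with an estimated correlation). Dendritic cell markers had a median of -0.87 (adjusted p = 0.0024; adjusted p = 0.313 with an estimated correlation), with CD1C at -1.49 ± 0.68. NK cell markers, of which 4 of 14 lie on another list, were higher (+0.38, adjusted p = 0.0020; adjusted p = 0.395 with an estimated correlation), but their score changed by +1.54 in L001 and -0.18 in L006, and by +0.07 ± 0.35 in the 4 L001 pairs without a doubted library. Medians for lists that did not pass were -0.39 for monocytes, -0.11 for neutrophils, +0.20 for gamma-delta and MAIT cells, +0.10 for CD4 and regulatory T cells, +0.01 for plasma cells, +0.17 for erythroid cells and +0.03 for platelets. More of these passed without the 10 doubted libraries, with -0.75 for monocytes (adjusted p = 1.4e-04; adjusted p = 0.507 with an estimated correlation) and -0.76 for neutrophils (adjusted p = 4.91e-04; adjusted p = 0.245 with an estimated correlation). In that set the B cell median was -0.74 and the dendritic cell median -1.11. In L006 monocytes had -0.067 (adjusted p = 0.752) and neutrophils -0.52 (adjusted p = 0.058). Only 3 of the 9 tested dendritic cell genes had a mean of at least 5 CPM over all libraries, so these medians rest largely on low counts. The B cell score changed by -0.56 in L006 and -0.33 in L001, and the dendritic cell score by -0.36 and +0.12 in these lanes. Summed B cell marker levels had low medians of 123.0 CPM at baseline, 105.7 at cycle 1 and 131.0 at cycle 2. The highest libraries, however, held 40910, 478.7 and 5014 CPM. For monocyte markers the highest values were 12420, 12490 and 13350 CPM. A CD8 sort gate would remove most cells of these types, but such values mark single libraries with many of their transcripts.

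Gene by gene, edgeR called 0 of 15553 genes at cycle 1 against baseline, with 406 (2.61%) at an unadjusted p under 0.05. That share is below the 0.05 that unchanged genes would give on average. The main test was thus likely conservative, and 0 calls do not show that no gene changed. The smallest adjusted p was 0.9997. DESeq2 called 0 (979 unadjusted, 6.29%), limma voom 0 (564, 3.63%) and limma with quality weights 6 (1547, 9.95%). The smallest p values belonged to ZNRF1 (+0.81 ± 0.26, p = 0.0030), TRIM59 (+0.55 ± 0.18) and WDR62, a spindle pole protein (+1.17 ± 0.40), and to the cytokine LTA (-0.70 ± 0.20, p = 9.5e-04), NOL4L (-0.63 ± 0.19) and the retinoic acid receptor RARA (-0.68 ± 0.22), which did not pass. Of 30 lists 18 passed, 12 higher and 6 lower, and 0 passed with an estimated correlation or with fry. With time labels shuffled within patients, up to 17 lists passed. In every list 0 members passed over all genes, and 0 passed when adjusted over the list alone.

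**Figure D3:**
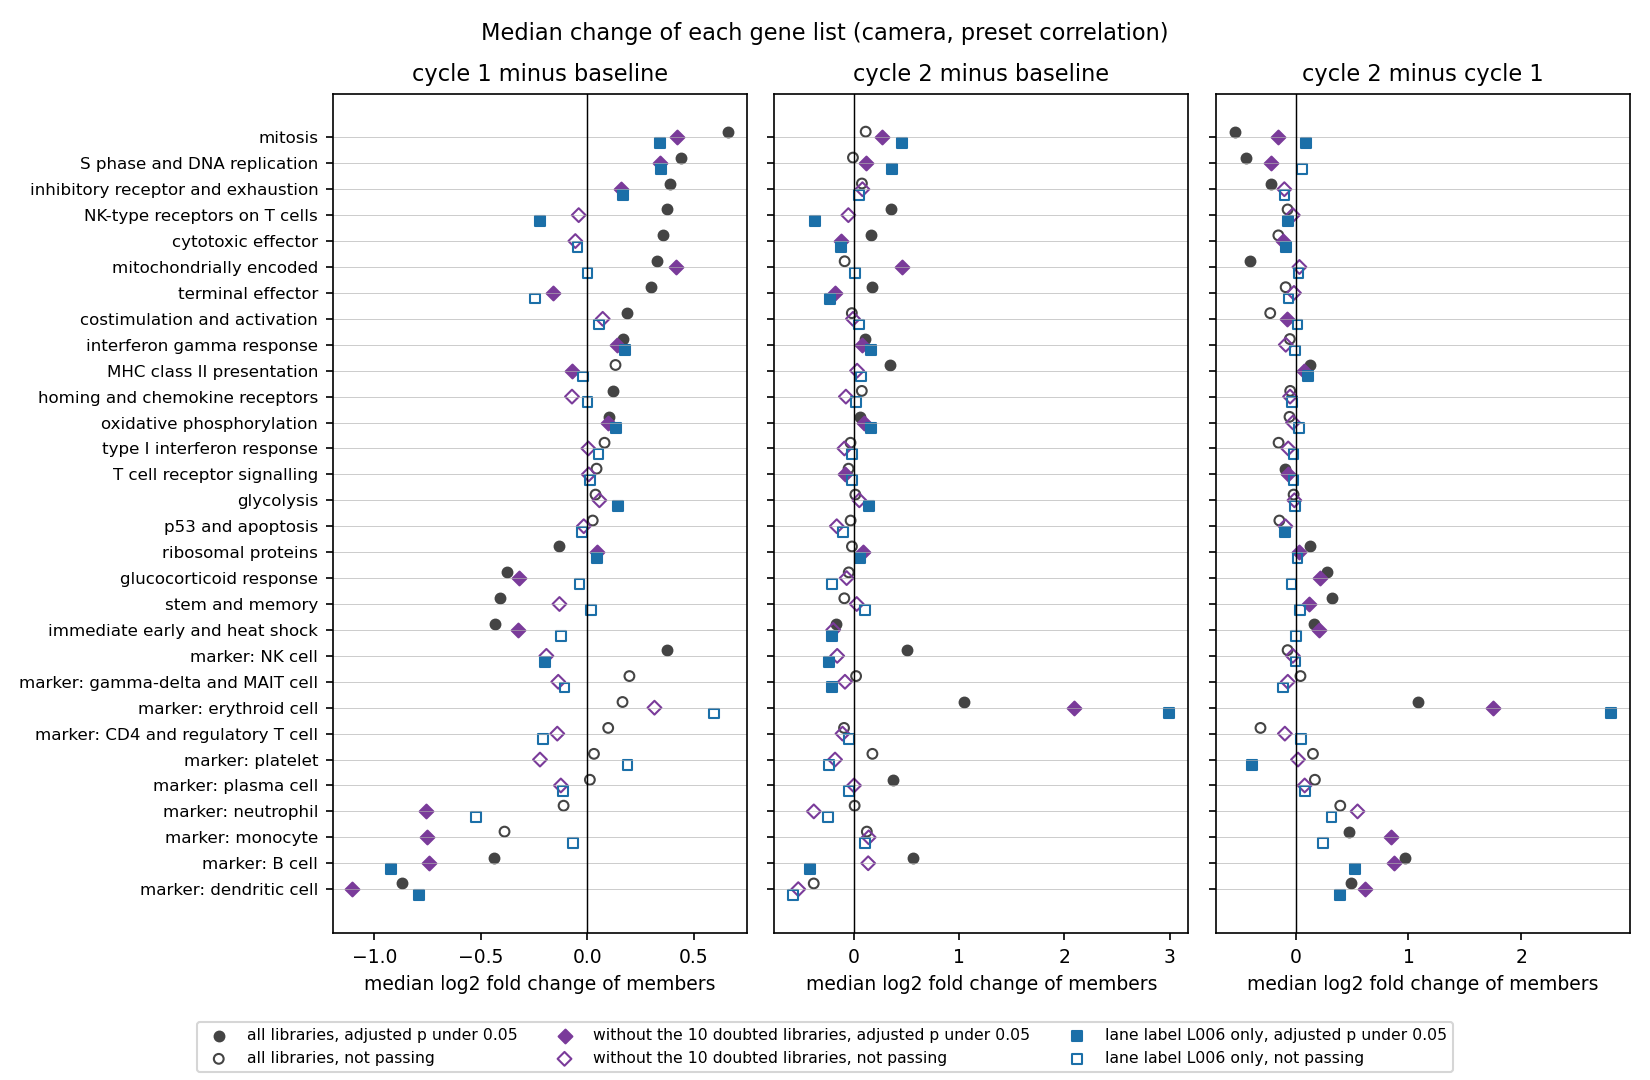
Median log2 change of each of the 30 gene lists in the 3 comparisons, with all libraries, without the 10 doubted libraries and in the 16 patients of L006; filled points have a camera adjusted p under 0.05. Mitosis at cycle 1 lies at +0.66, +0.42 and +0.34 in these 3 sets, while the terminal effector median goes from +0.30 to -0.16 without the doubted libraries.

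At cycle 2, antigen presentation genes were higher than at baseline over all libraries, and did not pass once the doubted ones were left out. The MHC class II list had 13 of 14 genes above baseline with a median of +0.34 (adjusted p = 3.41e-06; adjusted p = 0.609 with an estimated correlation), among them the peptide loading chaperone HLA-DMB (+0.39 ± 0.23, n = 20) and HLA-DQA1 (+0.39 ± 0.29). IFI30 had +0.96 ± 0.79 and HLA-DRA +0.25 ± 0.34. The list median was +0.029 without the 10 doubted libraries (adjusted p = 0.664) and +0.068 in L006 (adjusted p = 0.22). Interferon gamma response genes were slightly higher (median +0.11, 17 of 24, adjusted p = 0.0048; adjusted p = 0.609 with an estimated correlation), with GBP5 at +0.36 and the proteasome activator PSME2 at +0.27. Cytotoxic effector genes had +0.17 (adjusted p = 0.0048), NK-type receptors +0.35 (adjusted p = 0.0023), terminal effector genes +0.18 (adjusted p = 0.016) and oxidative phosphorylation genes +0.05 (adjusted p = 0.016). With an estimated correlation the adjusted p of each of these 4 lists was 0.784. The first 3 turned over without the 10 doubted libraries, to -0.12 for cytotoxic (adjusted p = 0.011), -0.054 for NK-type (adjusted p = 0.729) and -0.18 for terminal effector genes (adjusted p = 0.017), with adjusted p values of 0.683, 0.927 and 0.683 with an estimated correlation. In L006 they were -0.13 (adjusted p = 0.033), -0.37 (adjusted p = 1.01e-04) and -0.23 (adjusted p = 0.0046), with 0.65, 0.316 and 0.49 as adjusted p with an estimated correlation. Immediate early and heat shock genes were lower (median -0.17, 19 of 25 below baseline, adjusted p = 0.013; adjusted p = 0.784 with an estimated correlation), with PPP1R15A at -0.77 ± 0.34, and had -0.20 without the doubted libraries (adjusted p = 0.062).

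Cell division genes did not pass at cycle 2 over all patients. The mitosis list had a median of +0.11 (34 of 40 above baseline, adjusted p = 0.188), with MKI67 at +0.48 ± 0.49 and TOP2A at +0.65 ± 0.48. In the 13 L006 pairs, all 40 mitosis genes were above baseline (median +0.45, adjusted p = 2.14e-20; adjusted p = 0.23 with an estimated correlation), and 14 of them passed when adjusted over the list alone. The mitosis score there was +0.47 ± 0.13, higher in 11 of 13 patients (exact permutation p = 0.0056, adjusted p = 0.081). In L001 the list median was -1.38 (adjusted p = 4.69e-07; adjusted p = 0.676 with an estimated correlation). ITGAE, which keeps T cells in epithelium, was higher in 16 of 20 pairs (+0.47 ± 0.24). PDCD1 was at +0.21 ± 0.38, CTLA4 at +0.13 ± 0.37, GZMB at +0.40 ± 0.43, IFNG at -0.39 ± 0.40 and CD38 at +0.15 ± 0.40. With all libraries the S phase median was -0.01 in the limma fit although 32 of 35 genes had a positive change in edgeR. Its test had the other sign. In this comparison the medians and tests of the costimulation (-0.02), glucocorticoid (-0.05), neutrophil (+0.01), p53 (-0.03) and ribosomal (-0.02) lists also differed in sign, and none of these passed. The mitochondrially encoded list (-0.09) had 13 of 13 positive changes in edgeR.

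In the 16 patients of L006, limma with quality weights called 65 genes at cycle 2 against baseline, 39 higher and 26 lower, while edgeR called 0 there (1353 at an unadjusted p under 0.05) and DESeq2 5. Of the called genes 3 lie on the S phase list (POLE2, MCM6 and POLA1) and 1 on the mitosis list (BUB1). Single genes that rose were POLE2, a DNA polymerase epsilon subunit (log2 +0.63 ± 0.14, higher in 13 of 13 pairs), MCM6 of the replicative helicase (+0.48 ± 0.11), the spindle checkpoint genes BUB1 (+0.63 ± 0.15) and MAD2L1 (+0.48), and OIP5 (+0.74 ± 0.16). GBP1 rose as well (+0.52 ± 0.10). The killer cell receptor KIR3DL2 (-0.95 ± 0.22), the activating receptor NCR1 (-0.78 ± 0.17), KLRB1 (-0.66 ± 0.16), the transcription factor RORA (-0.38 ± 0.08) and the chloride channel CLCN2 (-2.002 ± 0.39, ENSG00000114859) fell. Adjusted p values ran from 0.022 to 0.049. Of 64 of these genes measured in L001, 21 had the same sign there. These genes and the subset were chosen after their values were seen.

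**Figure D4:**
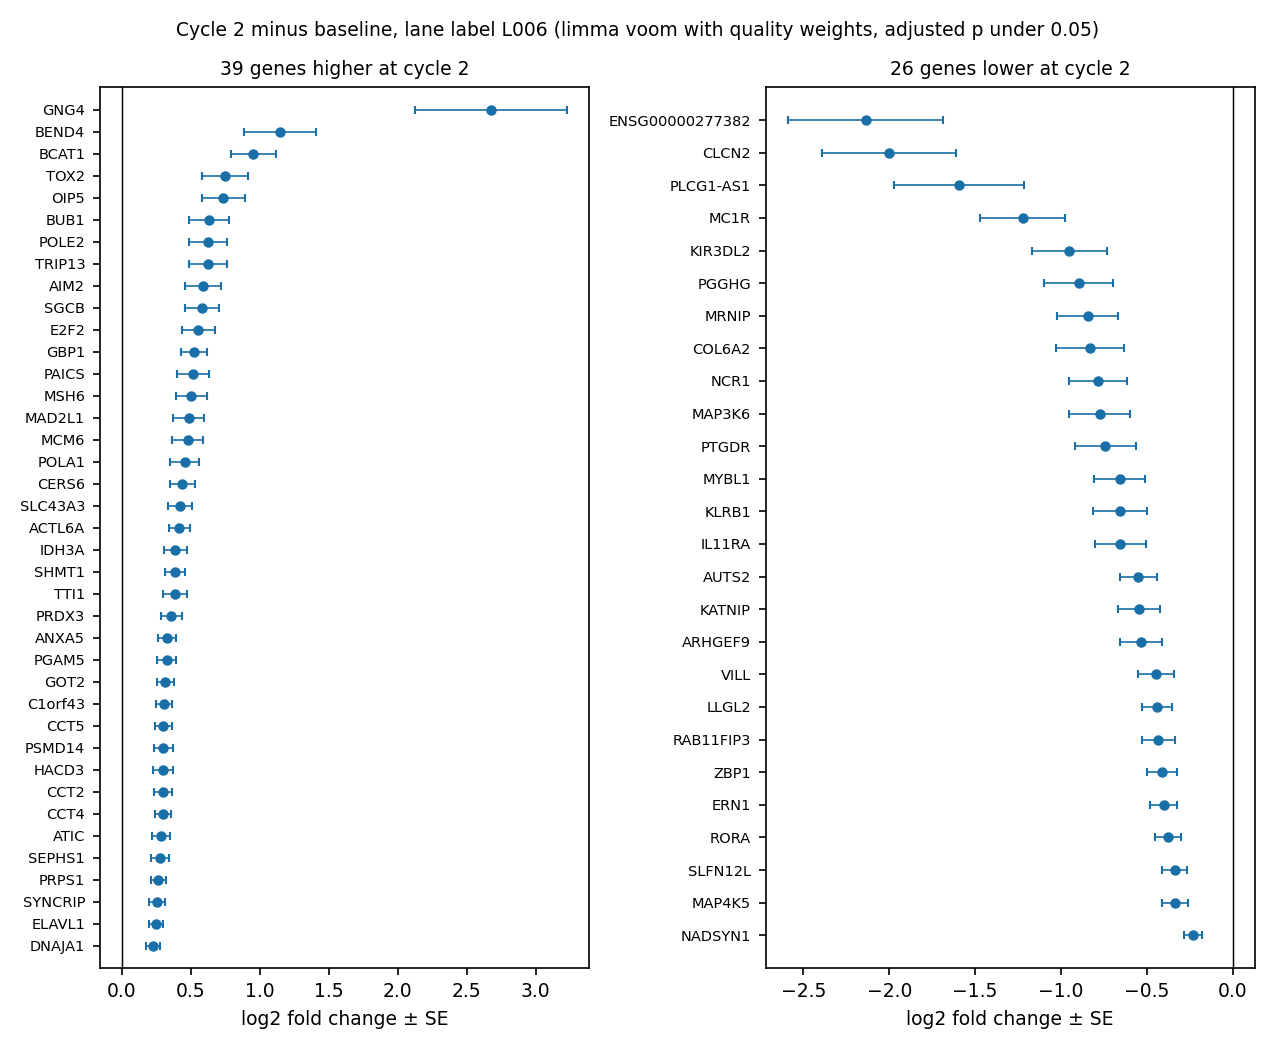
Log2 change from baseline to cycle 2 (± SE) of the 65 genes that passed in limma with quality weights in the 16 patients of lane label L006 (13 pairs). Above 0 lie 39 genes and below it 26, with GNG4 at +2.67 farthest above and ENSG00000277382, a gene without a symbol, at -2.14 farthest below.

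Markers of other cells at cycle 2 against baseline were higher for NK cells (median +0.50, adjusted p = 6.34e-04; adjusted p = 0.609 with an estimated correlation), B cells (+0.56, adjusted p = 0.0032; adjusted p = 0.784), plasma cells (+0.37, adjusted p = 0.017; adjusted p = 0.609) and erythroid cells (4 genes, +1.04, adjusted p = 0.024; adjusted p = 0.609), with TYROBP at +0.87 ± 0.48 and HBA2 at +1.89 ± 0.88. Medians without the 10 doubted libraries were -0.16 for NK cells, +0.13 for B cells (adjusted p = 0.524), -0.00074 for plasma cells and +2.10 for erythroid cells (adjusted p = 1.81e-04; adjusted p = 0.425 with an estimated correlation). In L006 the B cell median was -0.42 and the NK cell median -0.24. Summed erythroid markers had medians of 4.54 CPM at baseline and 4.397 CPM at cycle 2, with the highest libraries at 9510 and 824.6 CPM. Medians of lists that did not pass ran from -0.38 (dendritic cells) to +0.17 (platelets), with +0.12 for monocytes (adjusted p = 0.053), +0.07 for inhibitory receptors, -0.09 for stem and memory genes and -0.03 for type I interferon genes.

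Gene by gene, edgeR called 0 of 15553 genes at cycle 2 against baseline, with 290 (1.86%) at an unadjusted p under 0.05, again below a share of 0.05. Limma voom called 0 (359), DESeq2 1 (639) and limma with quality weights 2 (1970). With the weights GNG4 rose by 2.64 ± 0.44 and CLCN2 fell (-1.91 ± 0.32), each with an adjusted p of 0.0024 (edgeR +1.80 ± 0.71 and -2.19 ± 0.61), and DESeq2 called CLCN2 (-2.29 ± 0.49, adjusted p = 0.038). Both were named after their values were seen. Among the smallest edgeR p values, which did not pass, were those of the actin regulator kinase LIMK1 (+0.78 ± 0.26), TUT7 (+0.44 ± 0.15), DCTN6 (+0.51 ± 0.18), the RNA helicase DDX39B (-0.73 ± 0.26) and HSD17B8 (-0.76 ± 0.28). Of the 30 lists 11 passed, 10 higher and 1 lower, 0 with an estimated correlation or fry, and 0 members passed over all genes or adjusted over the list alone. Shuffled time labels gave up to 18 passing lists.

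From cycle 1 to cycle 2, division and replication genes were lower and memory genes higher over all patients. The mitosis list had a median of -0.54, with 39 of 40 genes below cycle 1 (adjusted p = 3.69e-11; adjusted p = 0.501 with an estimated correlation). The S phase list had -0.44, with 0 of 35 above cycle 1 (adjusted p = 3.69e-11; adjusted p = 0.501 with an estimated correlation). MKI67 had a log2 change of -0.42 ± 0.49 (n = 20), KIF11 -0.62 ± 0.39, the centromere histone CENPA -0.81 ± 0.48 and the replication clamp PCNA -0.55 ± 0.31. The stem and memory list had +0.32 (17 of 20 genes above cycle 1, adjusted p = 1.25e-07; adjusted p = 0.501 with an estimated correlation), with BACH2, a repressor that keeps T cells from terminal differentiation, at +0.77 ± 0.42 and CCR7 at +0.82 ± 0.47. The mitosis score changed by -2.01 in L001 and +0.08 in L006 (exact permutation p of the difference 0.0031, adjusted p = 0.024). In L001 it was -2.64 ± 1.15 in the 4 pairs with a doubted library and -1.17 ± 0.80 in the other 3. Leaving out the 10 doubted libraries gave medians of -0.15 for mitosis, -0.22 for S phase and +0.12 for stem and memory genes (adjusted p = 0.0017; adjusted p = 0.47 with an estimated correlation). In L006 they were +0.088, +0.054 and +0.039 (adjusted p = 0.047, 0.221 and 0.544; adjusted p = 0.855 for each with an estimated correlation).

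Inhibitory receptors were lower at cycle 2 than at cycle 1 (median -0.22, 16 of 22 genes below, adjusted p = 0.044; adjusted p = 0.501 with an estimated correlation), with PDCD1 at -0.51 ± 0.36, CTLA4 at -0.70 ± 0.37 and TOX at -0.44 ± 0.34. Their call ended without the 10 doubted libraries (-0.10, adjusted p = 0.074) and in L006 (-0.098, adjusted p = 0.108). T cell receptor signalling genes had -0.09 (adjusted p = 0.024; adjusted p = 0.501), with VAV1 at -0.33 and SH2D1A at -0.45. MHC class II genes were higher (+0.13, 13 of 14, adjusted p = 0.0016; adjusted p = 0.501), as were ribosomal proteins (+0.12, adjusted p = 4.05e-07; adjusted p = 0.501), glucocorticoid response genes (+0.28, adjusted p = 5.91e-05; adjusted p = 0.424) and immediate early genes (+0.16, adjusted p = 0.0078; adjusted p = 0.501). Here the adjusted p after each semicolon is with an estimated correlation. In L006 the medians that no longer passed were -0.019 for T cell receptor signalling, +0.016 for ribosomal proteins, -0.038 for glucocorticoid response and +0.0028 for immediate early genes (adjusted p = 0.23, 0.367, 0.205 and 0.247). The mitochondrially encoded list was lower in limma (-0.40, adjusted p = 0.029; adjusted p = 0.763 with an estimated correlation), while 12 of its 13 genes had a positive change in edgeR and its median was +0.033 without the doubted libraries (adjusted p = 0.547).

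B cell markers were higher at cycle 2 than at cycle 1, with 15 of 15 genes above (median +0.97, adjusted p = 3.37e-10; adjusted p = 0.424 with an estimated correlation), among them CD79A of the B cell receptor (+1.40 ± 0.65) and IGHM (+1.13 ± 0.63). Monocyte markers had +0.48 (adjusted p = 9.18e-05; adjusted p = 0.501), dendritic cell markers +0.49 (adjusted p = 0.029; adjusted p = 0.501) and erythroid markers +1.08 (adjusted p = 0.044; adjusted p = 0.501), again with the estimated correlation after the semicolon. Monocytes without the 10 doubted libraries had +0.85 (adjusted p = 1.09e-07; adjusted p = 0.445) and erythroid markers had +1.75 (adjusted p = 7.84e-04; adjusted p = 0.275). In L006 the B cell median was +0.52 with 15 of 15 genes above, and monocytes had +0.24 (adjusted p = 0.137). Of 30 lists 14 passed, 9 higher and 5 lower, and 0 with an estimated correlation or fry. Up to 17 lists passed with shuffled time labels, and 0 members passed over all genes or adjusted over the list alone. The glycolysis (-0.02), NK cell (-0.07) and gamma-delta and MAIT (+0.04) lists had a median that differed in sign from the test or the mean, and did not pass.

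Gene by gene, edgeR called 0 of 15553 genes between cycle 2 and cycle 1, with 157 (1.01%) at an unadjusted p under 0.05, again below a share of 0.05. Limma voom called 0 (305), DESeq2 1 (471) and limma with quality weights 1 (488). CLCN2 fell with the weights (-1.65 ± 0.30, adjusted p = 0.025; edgeR -1.56 ± 0.60; named after its value was seen), and the DESeq2 call was a gene without a symbol, ENSG00000256084 (-2.33 ± 0.48, adjusted p = 0.016). The smallest edgeR p values, not passing, were of RIPOR1 (+0.84 ± 0.28), the B cell survival receptor TNFRSF13C (+1.41 ± 0.51), NLRP6 (+1.503 ± 0.55), NEK10 (-2.65 ± 0.93), WWOX (-0.61 ± 0.22) and BLMH (-0.47 ± 0.20). In the joint test of any change over the 3 time points edgeR called 0 genes, with 210 at an unadjusted p under 0.05.

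The changes at cycle 1 and at cycle 2 against the shared baseline had a correlation of 0.554 across 15553 genes in 20 patients. Shuffled time labels gave a mean of 0.513 (0.266 to 0.779), so this is within what a shared baseline gives. In the 13 patients of L006 with 3 libraries it was 0.722, above the shuffled range (0.213 to 0.685). With the baseline libraries divided into 2 sets, 1 for each comparison, it was 0.225 there (0.0333 to 0.376) and -0.0083 over all 20 patients (-0.226 to 0.146). Genes are not independent replicates.

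Patients whose mitosis score went up more at cycle 1 lost more of the stem and memory score. Over 25 patients Pearson's r was -0.68 (permutation p = 2.4e-04, adjusted p = 0.0014 over 6 relations) and Spearman's rho -0.56 (p = 0.0040, adjusted p = 0.024). Without the 2 patients farthest from the median r was -0.64 (p = 0.0011). Within lanes it was -0.68 in L001 (n = 9, exact permutation p = 0.046, adjusted p = 0.258) and -0.36 in L006 (p = 0.17), so that it did not pass in either lane. Without the 10 doubted libraries it was -0.17 (p = 0.46). The cytotoxic score had r = 0.34 and rho = -0.26 over all patients, but r = -0.57 in L006 (rho -0.56, p = 0.020 and 0.028, adjusted 0.12 and 0.083) and r = -0.49 without the doubted libraries (rho -0.68, p = 0.0012, adjusted p = 0.0074). The inhibitory receptor score had r = 0.44 (adjusted p = 0.076), the terminal effector score 0.38, MHC class II 0.29 and type I interferon 0.21, none of which passed. Leaving out the 10 doubted libraries turned the first 2 to r = -0.57 (adjusted p = 0.048; rho -0.44, adjusted p = 0.108) and -0.45 (adjusted p = 0.090; rho -0.60, adjusted p = 0.018).

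The use of TRBV genes reflects the mix of T cell clones in a sample. Its breadth did not pass as changed over all pairs. It was broader after treatment in L006, a subset chosen after the data were seen. The Shannon entropy had means of 2.61 ± 0.57 (SD) at baseline, 2.77 ± 0.31 at cycle 1 and 2.89 ± 0.24 at cycle 2 over 68 libraries. Within patients it changed by +0.097 ± 0.102 (SE, n = 24) at cycle 1 (permutation p = 0.38) and by +0.28 ± 0.148 (n = 19) at cycle 2 (p = 0.075, adjusted p = 0.226), and by +0.066 ± 0.068 between the cycles (n = 18, p = 0.34). In L006 it rose by 0.165 ± 0.068 at cycle 1 (12 of 16 patients, exact permutation p = 0.029, adjusted p = 0.044). At cycle 2 it rose by 0.244 ± 0.098 there (11 of 13, exact p = 0.0090, adjusted p = 0.027). In L001 the changes were -0.039 ± 0.28 (n = 8, exact p = 0.92) and +0.359 ± 0.444 (n = 6, exact p = 0.5). The lanes did not differ by exact permutation (p = 0.37 and 0.73). The most used TRBV gene held a mean of 27.2% of TRBV counts at baseline, 23.6% at cycle 1 and 19.3% at cycle 2. With TRAV genes over all pairs, entropy changed by +0.125 ± 0.126 at cycle 1 (higher in 11 of 24, permutation p = 0.42). It changed by +0.178 ± 0.186 at cycle 2 (15 of 20, p = 0.35) and by -0.049 ± 0.111 between the cycles (p = 0.81).

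TRBV use stayed closer within a patient than between patients, with a mean similarity of 0.631 over 61 pairs against 0.469 (one-sided permutation p = 1e-04, the smallest possible). In L006 the values were 0.685 and 0.475 (p = 1e-04, the smallest possible), and the most similar library came from the same patient for 36 of 45 libraries. In L001 they were 0.51 and 0.46 (p = 0.024), with 7 of 23 libraries. Within patients the similarity was 0.659 between baseline and cycle 1, 0.553 between baseline and cycle 2 and 0.676 between the cycles.

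**Figure D5:**
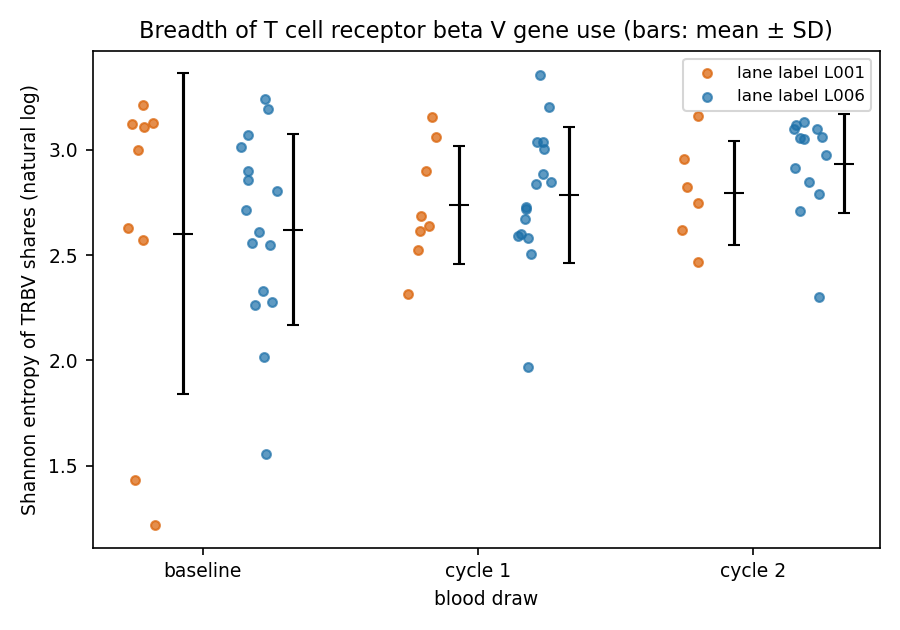
Shannon entropy (natural log) of TRBV gene use per library, thinned to 500 counts, by time point and lane label, with mean ± SD. Over both lanes the means are 2.61 at baseline, 2.77 at cycle 1 and 2.89 at cycle 2.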

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

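The tests of the mitosis changes without the 10 doubted libraries and within lanes, and of the calls without a patient block, were chosen only after the result was seen; the shuffles of time labels were planned, except those within the subsets.

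In 14 gene lists the camera test of cycle 2 against cycle 1 passed at the preset correlation, a number that shuffled time labels also reached. The median differences were -0.54 for mitosis, -0.44 for S phase and DNA replication, -0.22 for inhibitory receptors, -0.40 for mitochondrially encoded genes and -0.091 for T cell receptor signalling. They were +0.32 for stem and memory, +0.12 for ribosomal proteins, +0.28 for glucocorticoid response, +0.13 for MHC class II and +0.16 for immediate early genes. For markers of other cells they were +0.97 (B cells), +0.48 (monocytes), +0.49 (dendritic cells) and +1.08 (erythroid cells). None passed with an estimated correlation, where the smallest adjusted p was 0.424. Of the 13 mitochondrially encoded genes, 12 had a positive change in edgeR. In the 13 patients of L006 the mitosis and S phase scores changed by +0.08 and +0.03.

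Shuffling the time labels within patients gave the following. For lists at cycle 1 against baseline 1 of 21 splits, the real one, had 18 passing lists, against 17 at most in the others. As 3 comparisons were tried, 1 of 21 is the smallest share that 20 shuffles can give, and the margin is 1 list, so chance is not firmly excluded. At cycle 2 against baseline 14 of 21 splits had at least the 11 lists that passed (highest other 18), and between the cycles 4 of 21 had at least 14 (highest other 17), so chance was not excluded. With so many lists passing in shuffled data, a camera call at the preset correlation carries little weight here. For genes 21 of 21 splits had at least the real count of 0 in each comparison (highest other 0). With a real count of 0 that outcome was fixed in advance, so it does not bear on chance. Genes at an unadjusted p under 0.05 at cycle 1 without the doubted libraries numbered 877, and 2 of 21 splits had as many (highest other 891), so chance was not excluded. In L006 with quality weights 1 of 41 splits, the real one, had 65 genes at cycle 2 against baseline, against 4 at most in the others. These shuffles cover this setting alone, which was picked after the counts were seen, so they do not account for that choice.

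Mitosis transcripts were higher at cycle 1 than at baseline and lower at cycle 2 than at cycle 1. For the first part, whether the change lies in L001 alone cannot be decided. The mean score change in L006 was +0.32 ± 0.19 (n = 16, exact permutation p = 0.11), more than 1 SE above 0 but not passing. The L001 mean of +1.28 joins +1.77 ± 0.76 in 5 pairs that hold a doubted library with +0.67 ± 0.79 in the other 4. The latter lies within 1 SE of 0, so a difference between the lanes stays open. Poor or doubtful libraries stay open as well, because without the 10 doubted ones the change was +0.39 in place of +0.67. The lower value at cycle 2 may come from L001 alone, where it was -2.01 against +0.079 ± 0.20 in L006 (n = 13). Without the doubted libraries it was -0.15 ± 0.24 (n = 16) in place of -0.65, but that step also leaves out 4 of the 7 L001 pairs. The 3 L001 pairs without a doubted library had -1.17 ± 0.80, and -1.33 ± 0.39 for S phase, with 0 of 3 higher in each. As all doubted libraries carry L001, lane and doubt cannot be told apart as the source of the lower value. A biological rise in dividing cells after the first cycle stays open, as untested by outcome or dose.

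The calls made without the patient block may come from the 5 libraries that stand apart. With no block edgeR called 925 genes at cycle 1 against baseline over all libraries, and 0 without these 5 (654 at an unadjusted p under 0.05). Of the 5 libraries, 4 held over 50% mitochondrial counts. No biological explanation was tested for these calls.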

How the results depend on the processing

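The choice of the L006 and L001 lanes, of the 5 libraries that stand apart and of the 10 doubted ones, and limma voom without weights, came only after the data were seen; the other alternatives were planned. Of 13638 values of 474 results on single genes under the alternatives, 13532 kept their side of the threshold, 98 became passing and 8 changed sign with a call in at least 1 of the settings. Of the 13532, 1525 changed sign while passing in neither setting. Of 1260 list test medians 913 kept their side (113 of them changed sign while passing in neither), 79 became passing, 90 changed sign with a call in at least 1 of the settings and the rest no longer passed. Of 720 list scores 718 kept their side, 123 of them with another sign while passing in neither, and 2 became passing. Medians listed below as of another sign are those that passed in at least 1 of the 2 settings compared. The size of a change limits what single genes can show, and depth was not varied. In the simulated data the test found 35.8% of genes changed 1.5-fold but 95.5% of those changed 2-fold. Those data held no failed samples and had a smaller spread than the real ones. The shares are therefore not the power of the test on the real libraries. Except where a clause says so, the cause was not tested for any value below.

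The counts of genes called by edgeR moved without the patient block, to 925 at cycle 1 against baseline, 790 at cycle 2 against baseline and 423 between the cycles. Without the 5 libraries that stand apart, the same model with no block called 0 genes in each comparison, against 654, 224 and 496 at an unadjusted p under 0.05. With no low count filter the counts were 84, 20 and 82 of 52030 genes. Limma with quality weights called 6, 2 and 1 on all libraries, 2, 3 and 2 without the 5 libraries, and 2, 3 and 0 without the 10 doubted ones. Without weights limma called 6 genes at cycle 1 without the 5 libraries, 1 without the 10 and 1 in L006. In L006 the weights gave 3 genes at cycle 1 and 65 at cycle 2 against baseline, and DESeq2 gave 3 and 5. DESeq2 called 1 gene at cycle 2 against baseline and 1 between the cycles, on all libraries and without the doubted ones alike. In L006 the weights gave KIR3DL2 -0.95, NCR1 -0.78, PTGDR -0.74 and KLRB1 -0.66 at cycle 2 against baseline, against positive values over all patients. With no block MT-ND3 had -4.04, MT-ND2 -3.64, MT-ND6 -4.10 and MT-ND4 -3.71 between the cycles, where the block gave positive values.

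The number of passing lists went from 18, 11 and 14 to 0 in each comparison with an estimated correlation and with fry, in the main setting. With an estimated correlation 3 lists passed in each comparison with no low count filter. With only the patients with all 3 time points, 1 did at cycle 1 (adjusted p = 0.016). In L006 fry passed 2 lists at each cycle against baseline. At the preset correlation the number was 19 at cycle 2 against baseline with no low count filter and 18 there without the 5 libraries. In L006 it was 11 at cycle 1 against baseline and 9 between the cycles. Without the 10 doubted libraries and with no block, 7 lists passed at cycle 1 and 6 between the cycles.

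Without the 10 doubted libraries, list medians of another sign at cycle 1 against baseline were the following, each with TMM and then RLE size factors: -0.056 and -0.068 for cytotoxic effector, -0.072 and -0.089 for homing, -0.19 and -0.21 for NK cell markers, -0.074 and -0.086 for MHC class II, -0.041 and -0.048 for NK-type receptors, 0.047 and 0.035 for ribosomal proteins and -0.16 and -0.17 for terminal effector. At cycle 2 against baseline these pairs were -0.12 and -0.11 for cytotoxic effector, -0.16 and -0.15 for NK cell markers, -0.00074 and -0.0029 for plasma cell markers, 0.45 and 0.47 for mitochondrially encoded, -0.054 and -0.060 for NK-type receptors, 0.082 and 0.093 for ribosomal proteins, 0.11 and 0.12 for S phase and -0.18 and -0.17 for terminal effector. Between the cycles the pair was 0.033 and 0.059 for mitochondrially encoded. With no replicate block as well, medians at cycle 1 were -0.036 for cytotoxic effector, -0.023 for homing, -0.040 for inhibitory receptors, -0.039 for NK cell markers, -0.043 for NK-type receptors, 0.038 for ribosomal proteins and -0.10 for terminal effector. At cycle 2 against baseline they were -0.21 for cytotoxic effector, -0.28 for B cell markers, -0.29 for erythroid cell markers, -0.058 for NK cell markers, -0.12 for plasma cell markers, 0.14 for mitochondrially encoded, -0.17 for NK-type receptors, 0.22 for S phase, 0.19 for stem and memory and -0.21 for terminal effector. Between the cycles that setting gave 0.10 for glycolysis, 0.11 for mitosis, -0.041 for ribosomal proteins and 0.091 for S phase.

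In L006 alone, medians of another sign at cycle 1 against baseline, with a pass in at least 1 setting, were -0.047 for cytotoxic effector, -0.20 for NK cell markers, -0.22 for NK-type receptors, 0.047 for ribosomal proteins, 0.018 for stem and memory and -0.25 for terminal effector. For cycle 2 against baseline L006 gave -0.13 for cytotoxic effector, -0.42 for B cell markers, -0.21 for gamma-delta and MAIT markers, -0.24 for NK cell markers, -0.052 for plasma cell markers, -0.37 for NK-type receptors, 0.057 for ribosomal proteins, 0.36 for S phase and -0.23 for terminal effector. Between the cycles it gave -0.038 for glucocorticoid, -0.38 for platelet markers, 0.025 for mitochondrially encoded, 0.088 for mitosis and 0.054 for S phase. In L001 alone the median at cycle 1 was -0.20 for glycolysis and 0.25 for B cell markers. At cycle 2 against baseline L001 gave -0.024 for interferon gamma, -0.19 for erythroid cell markers, -1.38 for mitosis and -0.20 for oxidative phosphorylation, and between the cycles -0.070 for erythroid cell markers. Without the 5 libraries that stand apart, medians at cycle 2 against baseline were 0.48 for mitochondrially encoded and 0.21 for S phase, and between the cycles 0.13 for mitochondrially encoded. With no patient block and all libraries they were -0.16 for erythroid cell markers and 0.15 for S phase against baseline and -0.013 for MHC class II between the cycles. With no low count filter they were -0.0093 for gamma-delta and MAIT markers against baseline, and -0.026 for dendritic cell markers, -0.027 for gamma-delta and MAIT markers and -0.046 for plasma cell markers between the cycles.

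List scores per patient passed for 1 list at cycle 1 in L006, and for 1 list with the median over members. TRBV entropy changed by 0.165 at cycle 1 and 0.244 at cycle 2 in L006, which passed. Without the 10 doubted libraries it changed by 0.129 at cycle 1 (permutation p = 0.034, adjusted p = 0.102). Without the 5 libraries that stand apart the changes were 0.026 at cycle 1 (p = 0.74) and 0.109 at cycle 2 (p = 0.30). With a minimum of 200 counts they were 0.148 at cycle 2 against baseline (p = 0.40) and -0.044 between the cycles (p = 0.72). The agreement of the changes was 0.722 in L006 and -0.0083 with the baseline libraries divided into 2 sets. The pairing correlation was 0.0583 in L001.

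Pearson's r of the mitosis score with the stem and memory score was -0.36 in L006, -0.68 in L001 (9 patients) and -0.17 without the 10 doubted libraries, where it no longer passed. Leaving out the 2 farthest patients as well it was 0.17. With the cytotoxic score r was 0.50 without the 5 libraries, 0.54 without these and the 2 farthest patients, 0.44 with a pseudocount of 0.25 and -0.57 without the 10 and the 2 farthest. The inhibitory receptor score had 0.55 without the 2 farthest patients, 0.53 with a pseudocount of 0.25 and -0.57 without the 10. The terminal effector score had 0.47 without the 5 libraries, 0.51 with that pseudocount and -0.68 without the 10 and the 2 farthest. MHC class II had 0.51 without the 5, 0.502 without the 5 and the 2 farthest, and 0.52 without libraries of low total.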

Other observations

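The tests of the tumour-resident list and all values within L006 were chosen only after the result was seen, while the tests with a mitosis covariate and of CD4 and FOXP3 were set down before their values were computed.

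Within the 16 patients of L006, limma with quality weights called several single genes of metabolism and protein folding at cycle 2 against baseline, picked here from the 65 after their values were seen. The actin- and tubulin-folding chaperonin subunits CCT4 (log2 +0.30 ± 0.06, higher in 12 of 13 pairs), CCT5 (+0.30 ± 0.06, 13 of 13) and CCT2 (+0.30 ± 0.07, 13 of 13) rose. So did the purine synthesis enzymes PAICS (+0.52 ± 0.12, 12 of 13), ATIC (+0.28 ± 0.06, 13 of 13) and PRPS1 (+0.26 ± 0.06, 11 of 13). BCAT1, which transfers the amino group of branched-chain amino acids, had +0.95 ± 0.17 (11 of 13), the serine and glycine enzyme SHMT1 +0.39 ± 0.07, and ACTL6A, a chromatin remodelling subunit, +0.42 ± 0.07 (13 of 13). AIM2, a sensor of cytosolic DNA, had +0.59 ± 0.13 and the relative of TOX, TOX2, +0.75 ± 0.17. Among genes that fell were the stress sensor ERN1 (-0.40 ± 0.08), the MYB relative MYBL1 (-0.66 ± 0.15, higher in 1 of 13), the prostaglandin D receptor PTGDR (-0.74 ± 0.18) and COL6A2 (-0.83 ± 0.20). No enrichment was tested, so no group change is claimed, and 10 of the 65 called genes lie on a list fixed in advance.

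In L006 oxidative phosphorylation had 34 of 34 genes above baseline at cycle 1 (median +0.13, camera adjusted p = 8.55e-11; adjusted p = 0.229 with an estimated correlation) and 34 of 34 at cycle 2 (+0.16, adjusted p = 6.91e-13; adjusted p = 0.23 with an estimated correlation). Glycolysis had a median of +0.14 at both, with a fry adjusted p of 0.029 and 0.040, and 2 and 6 members passed when adjusted over the list alone. With an estimated correlation its camera adjusted p was 0.082 and 0.122, and in L001 its median at cycle 1 was -0.20 (adjusted p = 0.043). Interferon gamma genes had +0.18 and +0.16, with the same fry adjusted p values, and 2 members passed at each when adjusted over the list alone. With an estimated correlation their camera adjusted p was 0.078 and 0.122. NK-type receptors were lower at cycle 2 (-0.37, adjusted p = 1.01e-04, or 0.316 with an estimated correlation). Their score went the other way in L001, by +1.18 against -0.20 in L006 (exact permutation p = 0.012, adjusted p = 0.18). Of the 7 L001 pairs, 6 hold a doubted library.

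A hypothesis from the rise of GNG4, CXCL13 and CTLA4 was that cells with a tumour-resident CD8 profile entered the blood after the first cycle. A list of 20 genes described for such cells was written from textbook knowledge after those genes had been seen, so it is not independent evidence, and 13 of its genes lie on the fixed lists, 9 of them on the inhibitory receptor list. Its score was higher at cycle 1 by +0.49 ± 0.12 (18 of 25 patients, permutation p = 4.5e-04), by +0.31 ± 0.09 without the 10 doubted libraries (14 of 20, p = 0.0020) and by +0.39 ± 0.10 in L006 (13 of 16, exact p = 0.0017). In L001 it was +0.65 ± 0.30 (5 of 9, exact p = 0.11), and at cycle 2 over all pairs +0.16 ± 0.23 (n = 20, p = 0.50). Without the doubted libraries the fry p was 0.0014, with a median of +0.34.

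With the mitosis score as a covariate the median of that list was +0.34 (0.338) and the fry p 0.0056. The kept median shows only that adjusting for this score did not lower the change of the list. The test was set to need a passing fry p as well. More dividing cells in the sort therefore stay open as a source. The fry p cannot count as evidence, because the list was written after GNG4, CXCL13 and CTLA4 had been seen to rise. Of its 19 tested genes, 10 had a mean of at least 5 CPM. CD4 or regulatory T cells in the sort, which share CTLA4 and TIGIT, stay open: without the doubted libraries FOXP3 changed by -0.41 ± 0.88 and CD4 by -0.67 ± 0.59, errors too wide to decide. Sorting by CD8 would remove these cells. A rise of tumour-resident type CD8 T cells in blood may account for the pattern, but no T cell receptor sequence or tumour sample was at hand to test it.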
